A study of Mus musculus with 39 samples.

How the data were processed

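Stranded mRNA libraries (TruSeq, read on a NextSeq 2000 at 51 bp) of C2C12 cells with and without a Flnc knockout were used from 5 days of differentiation. The deposited table holds raw counts of reads per gene, which the authors made by checking reads with FastQC 0.11.9, aligning with STAR 2.7.9 and counting with featureCounts 2.0.3. The labels name the builds GRCm38 and GRCh38 without a role for the second, name DESeq2 without a version, and give neither the strand setting nor the gene annotation. All 29980 gene identifiers of the table matched GENCODE mouse release 21 on GRCm38, which gave symbols and positions, and 20960 of them are protein-coding. A column of the table that matched no sample was left out (1 column), and no library was left out of the analysis.

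Even values outnumbered odd ones: of 560803 values above 0, 64.4% were even (59.7% to 77.7% by library), with 7957 values of 1, 34526 of 2, 3670 of 3 and 17927 of 4. The deposited counts may therefore hold both mates of most read pairs separately, so depth in fragments is uncertain, and an alternative with every count halved was run. Library totals ranged from 6838281 to 28902526. Group means ± SD, in M counts, were 26.8 ± 2.78, 20.9 ± 4.04, 22.4 ± 3.56, 16.5 ± 3.43 and 11.5 ± 3.64 for WT days 0, 1, 2, 4 and 6, and 24.1 ± 3.38, 18.3 ± 4.02, 20.3 ± 3.83, 15.3 ± 4.72 and 10.2 ± 3.76 for KO. Depth was lower at day 6 than at day 0 in both lines.

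Samples were grouped by genotype and day from their labels. Counts were fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) in a single model with 1 mean for each of the 10 groups, TMM normalization (factors 0.904 to 1.05), filterByExpr by group, robust quasi-likelihood dispersions and F-tests. Of the genes, 10001 had no read and 13780 passed the filter and were tested; 29 residual degrees of freedom remained and the common biological coefficient of variation was 0.326. Contrasts were KO against WT on each day, each later day against day 0 within each line, and genotype by day against day 0 and over all days together. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Fold changes are those of the edgeR fit, and each SE is the square root of the summed variances of log2 CPM (prior count 2) over group sizes. Filamins were also tested by exact permutation of the libraries of a day.

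Fixed lists of genes (25 lists, 572 genes), written before the data were examined, were tested with camera on log2 CPM at its preset correlation of 0.01, adjusted over all 25 lists and all contrasts of the same kind (KO against WT, day against day 0, or genotype by day). Camera with a correlation estimated from the data called 0 lists in every contrast, and its value is given beside each call. Members were also counted after adjustment over the list alone. A gene with 0 counts in a group was compared through a floor of 3 counts over the group (6 counts, and bounds 0.5 times as large, if mates were counted separately), and genes with 1 to 3 counts in a group are given as CPM; intervals and floors cover counting error only. Named genes were chosen by a rule fixed before the data were examined: the 8 largest changes in each direction among called genes with at least 5 CPM over both groups and no overlap between groups, up to 4 members with the smallest p of each list described, and 18 genes of filamins, myogenesis and the cell cycle named in advance. Results of some genes are not reported here.

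Replicate numbers recur across groups. Whether libraries of the same number deviate together was checked by correlating deviations from the group mean, with a pairing accepted for a contrast when every pair exceeded r = 0.1. Pairs held for KO against WT at day 0 (0.14 to 0.44), day 1 (0.44 to 0.74), day 2 (0.21 to 0.58) and day 4 (0.20 to 0.74), and not at day 6, where replicate 3 gave -0.11. They also held for day 1 against day 0 in both lines and for day 2 against day 0 in the KO, and for no other contrast. The model without a block was fixed in advance and kept.

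Alternatives fixed before the data were examined were DESeq2 size factors, no filter, DESeq2 1.42.0, a replicate block, a fit of only the groups of the contrast, glmTreat against a 1.5-fold change, a prior count of 0.5, the estimated correlation, fry, and leaving out each library in turn. Alternatives added after seeing the data were a replicate block within each day, leaving out the 2 libraries that stand apart, and halved counts. All 35 splits of the libraries of each comparison of 2 groups, and 100 draws for genotype by day, each with the real grouping included, were fitted in the same way.

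The fit was tested on simulated data of 13780 genes with the observed depth and spread. For KO against WT at day 2, the comparison with 3 KO libraries, it recovered 1.49% of 1.5-fold, 28.4% of 2-fold and 81.8% of 4-fold changes, and for KO day 2 against day 0 it recovered 2.99%, 25.4% and 83.3%. For genotype by day at day 2 it recovered 0%, 5.97% and 69.7%, and over all days together 0%, 5.97% and 66.7%. Of 80, 80, 52 and 51 genes called in these, 5, 5, 2 and 3 had no simulated change. In KO against WT at day 0 and WT day 6 against day 0, without any simulated change, 0 genes were called. Changes were placed in KO day 2 alone, in 67, 67 and 66 genes at 1.5-, 2- and 4-fold beside a small list raised 1.5-fold. The real comparison of KO against WT at day 2 called 2467 genes. The Benjamini-Hochberg cutoff is stricter when fewer genes change, so recovery in the real data may be higher. No pairing by replicate number was simulated. Figures and tables were made with Python 3.11.15.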

Results

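Messenger RNA was sequenced in 39 libraries of C2C12 cells, a mouse myoblast line that leaves the cell cycle and fuses into multinucleated myotubes when serum is withdrawn. Wild-type (WT) cells and cells with a CRISPR knockout (KO) of Flnc, guided to its first exon, were collected in growth (day 0) and on days 1, 2, 4 and 6 of differentiation in 2% horse serum. Flnc encodes filamin C, the muscle filamin, an actin crosslinker of the Z-disc and of cell-matrix junctions. Each of the 10 groups of genotype and day held 4 libraries, except KO day 2 with 3. Total counts per library ranged from 6838281 to 28902526, and group means ran from 26.8 M ± 2.78 (SD, n = 4) at WT day 0 to 10.2 M ± 3.76 (n = 4) at KO day 6. The replicates are numbered, but the labels do not say whether they are separate cultures. Each edgeR p-value measures the spread between these samples, estimated over all 10 groups together, whereas each SE uses only the groups compared. Camera p-values compare the genes of a list with the other genes at a preset correlation of 0.01. All libraries of a genotype stem from cells called by the same name, so a difference between the KO and WT lines that arose outside Flnc is included in every KO against WT comparison. Values below are log2 differences from the edgeR model with the SE of the difference between the group means of log2 CPM (counts scaled to library totals). Levels are mean CPM ± SD, with n = 4 unless given. The 8 genes with the largest change in each direction were named only where the libraries of the 2 groups did not overlap. For these genes every KO library lay beyond every WT library of the day.

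Libraries differed by day and by genotype. Principal components were taken over genes above a minimum mean count, without TMM normalization. The first held 41.7% of the variance and ran from day 0 to day 6 in each line, and the second held 24.2% and separated KO from WT libraries. Both axes mixed day and genotype. On the first, KO day 6 libraries reached 24.3 to 38.0, against 74.2 to 90.0 for WT day 6. On the second, KO libraries moved from -6.22 to 12.8 at day 0 up to 48.2 to 62.0 at day 6. KO day 1 replicate 3 and WT day 0 replicate 4 stood apart from their groups, with mean correlations of 0.898 and 0.939 with the other libraries of the group. The share of counts from mitochondrial genes was higher in KO than in WT at day 6, at 5.24% ± 0.885 against 3.17% ± 0.298, and each KO library lay above each WT library.

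**Figure D1:**
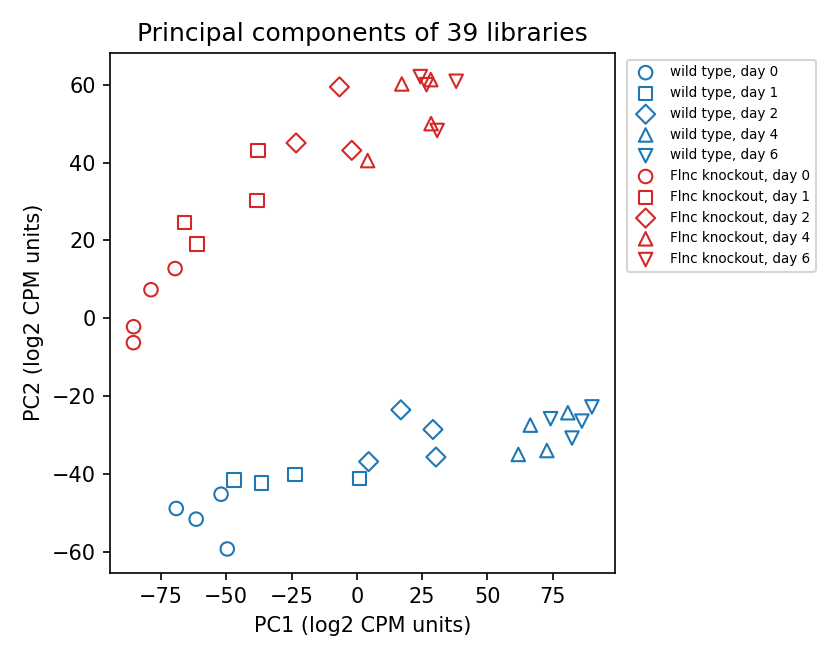
First and second principal components of log2 CPM for the 39 libraries, with points colored by genotype and shaped by day. The axes hold 41.7% and 24.2% of the variance, and KO libraries lie above WT libraries of the same day on the second axis.

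Flnc RNA itself was strongly lower in every KO library on every day. WT cells raised Flnc during differentiation, from 672 CPM ± 239 at day 0 to 1639 ± 266 at day 6, and KO cells went from 29.4 ± 17.4 to 118 ± 21.9. The KO level was 4.37% of the WT level at day 0, 6.78% at day 1, 6.60% at day 2 (n = 3 KO), 7.63% at day 4 and 7.20% at day 6. The Flnc gene (ENSMUSG00000068699; GRCm38 chromosome 6, 29433256 to 29461883, plus strand) was lower in the KO by 22.9-fold at day 0 and 13.9-fold at day 6, with adjusted p between 6.3e-10 at day 0 and 3.1e-08 at day 2 (edgeR). An exact two-sided permutation test on log2 CPM gave p = 0.0286 on each day, the smallest value that 4 against 4 or 4 against 3 libraries allow in this test. It exchanged the libraries of a day freely and ignored the pairing by replicate number that held at days 0, 1, 2 and 4.

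Filamin RNA outside Flnc also differed late in differentiation. Flna, the broadly expressed filamin A (ENSMUSG00000031328; chromosome X, 74223461 to 74249820), fell in WT cells from 5373 CPM ± 2411 at day 0 to 415 ± 165 at day 6. It was 1178 ± 224 in KO cells at day 6, a log2 difference of 1.505 ± 0.31 (adjusted p = 0.00173) with all 4 KO libraries above all WT libraries. At day 4 the Flna difference was 0.92 ± 0.39 and missed the threshold (adjusted p = 0.0532), which it passed with replicate number as a block (0.96, adjusted p = 0.00826). At days 0, 1 and 2 it was -0.67, -0.54 and -0.19. The increase of the Flna difference between day 0 and day 6 was tested directly and was 2.18 ± 0.57 on the log2 scale (adjusted p = 0.00417).

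**Figure D2:**
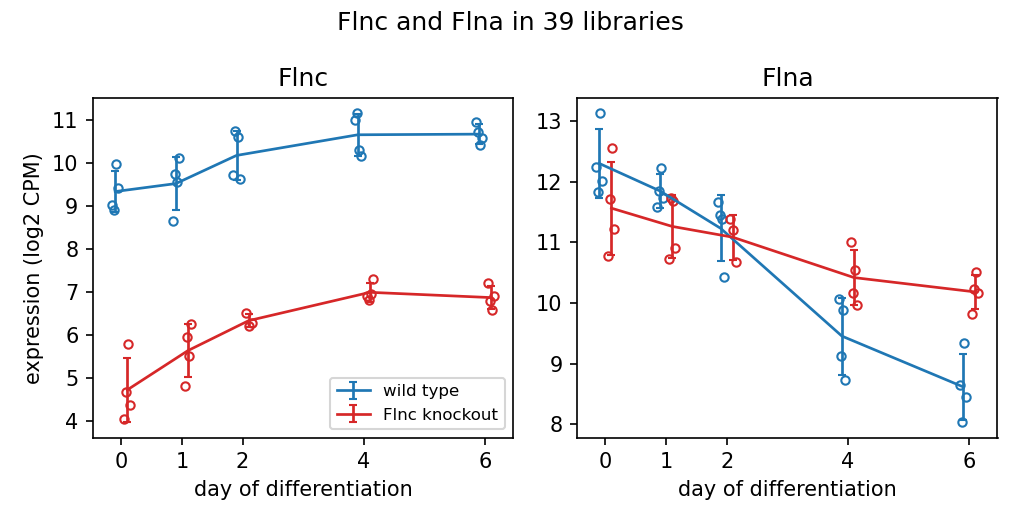
Log2 CPM of Flnc and Flna by day; points are libraries and lines join group means with the SD as bars. Flnc stays at 4.37% to 7.63% of the WT level in the KO, while Flna lies above WT at day 6.

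The comparison at day 0 asks how the lines differ before differentiation starts. KO myoblasts already held less RNA of muscle genes, of acetylcholine receptor subunits and of several glucose-metabolism genes, and single genes differed by large factors. Rhox5, a homeobox gene of the X-linked reproductive cluster, rose from 0.253 CPM ± 0.11 to 213 ± 80.3 (9.67 ± 0.36). The R-spondin Rspo2 rose by 8.18 ± 0.79 and the secreted Wnt modulator Sfrp2 by 6.21 ± 0.65 (2.56 CPM ± 1.49 to 189 ± 85.7). Also among the 8 largest increases were Meox2, a mesoderm homeobox gene (8.82 ± 0.64), Magea6 (8.81), Cntn3 (7.56), Tph2 (6.43) and Kank4os (6.25). Of these, Magea6 belongs to a family of near-identical copies. The largest decreases were in Hhip, the hedgehog-interacting protein (-8.52 ± 0.53; 55.01 CPM ± 21.5 to 0.140 ± 0.146), the growth cone protein Gap43 (-8.43 ± 0.66) and the neurotrophin receptor Ngfr (-8.18 ± 0.50). They were followed by Cdh11, a mesenchymal cadherin (-7.71 ± 0.53), Add2 (-8.15), Chmp4c (-8.01), Setbp1 (-7.89) and the mast cell protease gene Mcpt8, at 10.95 CPM in WT and 0.0213 in KO.

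Of 13780 genes tested at day 0, 890 were higher and 1252 lower in the KO. The sarcomere list had 14 of 35 measured members lower and 0 higher (17 and 0 adjusted over the list alone; median -1.45), among them Tnni1 (-2.67), Myom2 (-2.02 ± 0.47) and Actc1 (-2.79 ± 1.16). For the sarcomere list, camera gave adjusted p = 1.39e-04, and adjusted p = 0.788 with an estimated correlation. Genes of myoblast fusion fell in 6 of 18 cases with 0 higher (9 lower and 1 higher adjusted over the list alone), including the fusogen Mymk (-2.08 ± 0.68, lower in 3 of 4 samples than in all WT), the laminin receptor Itga7 (-1.41 ± 0.22), Jam2 (-1.69 ± 0.38) and M-cadherin, Cdh15 (-0.97 ± 0.27). For the fusion list, camera gave adjusted p = 0.00356, and adjusted p = 0.707 with an estimated correlation. Of 28 Z-disc genes and filamin C partners, 9 were lower and 1 higher (10 and 1 adjusted over the list alone), led by the filamin C ligands Xirp1 (-2.80 ± 0.53) and Xirp2 (-4.73 ± 0.78) and by Ankrd1 (-1.36 ± 0.28). For the Z-disc list, camera gave adjusted p = 0.00146, and adjusted p = 0.763 with an estimated correlation. The excitation-contraction coupling and endplate list had 6 of 25 lower and 1 higher (9 and 2 adjusted over the list alone), with the receptor subunits Chrnd (-2.97 ± 0.38) and Chrnb1 (-1.08 ± 0.27). For the coupling list, camera gave adjusted p = 0.04998, and adjusted p = 0.854 with an estimated correlation. The hypoxia and glycolysis list had 6 of 25 lower and 0 higher (6 and 0 adjusted over the list alone), with the lactate exporter Slc16a3 (-5.66 ± 0.79), Vegfa (-1.33 ± 0.13), Hk2 (-1.76 ± 0.18) and Pfkp (-1.18 ± 0.23). For the hypoxia list, camera gave adjusted p = 0.0284, and adjusted p = 0.788 with an estimated correlation. The oxidative phosphorylation list shifted upward by a median of 0.40 (camera adjusted p = 0.00479, and adjusted p = 0.893 with an estimated correlation). Of its 32 genes 0 passed the edgeR test over all genes or adjusted over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 1. Myod1, which encodes the myoblast-determining factor, was at 173 CPM ± 55.7 in WT and 171 ± 34.6 in KO, a difference of -0.02 ± 0.26.

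The day 0 muscle values depended on single libraries. Without WT day 0 replicate 5 the number of genes called fell from 2142 to 1393 and that of sarcomere genes from 14 to 3 (7 without KO day 0 replicate 3 or 5, 9 without replicate 1). Myog (-2.16 ± 1.04, adjusted p = 0.00886) was then at -1.54 (0.0851), and in a fit of the day 0 libraries alone at -2.15 (0.0672). The list call for excitation-contraction coupling was lost without WT replicate 4 (0.122) or 5 (0.133) or KO replicate 3 (0.111) or 5 (0.163), and its 6 lower genes were 10 without KO replicate 4. Halved counts ended the coupling call as well (0.0576). Its 1 higher gene became 2 without WT replicate 4 or KO replicate 5, and 1 fusion gene was higher without WT replicate 1. The call for oxidative phosphorylation was lost without KO replicate 3 (0.0915) and that for hypoxia without WT replicate 4 (0.171) or KO replicate 4 (0.0518) or 5 (0.0813). With fry, which asks whether the genes of a list move one way on balance, the sarcomere (0.0583), coupling (0.0703) and oxidative phosphorylation (0.239) lists were not called. Blocking by replicate number within the day raised the genes called to 3996.

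One day after serum withdrawal, KO cells held less RNA of contractile genes than WT cells, as at day 0. Myog, the myogenin gene, was at 179 CPM ± 130 in WT and 29.0 ± 23.0 in KO (-2.63 ± 0.77, adjusted p = 0.00127). The embryonic myosin Myh3 was at 173 ± 244 and 8.05 ± 7.90 (-4.41 ± 1.22), skeletal actin Acta1 at 374 ± 399 and 56.2 ± 26.8 (-2.73 ± 0.86) and muscle creatine kinase Ckm at 29.7 ± 33.8 and 3.25 ± 1.85 (-3.18 ± 0.96). Each of these was lower in all 4 KO libraries than in all 4 WT libraries, as were Mymk (-3.20 ± 0.66, adjusted p = 1.83e-05), Xirp1 (-3.33 ± 0.48) and the cell cycle inhibitor Cdkn1a (-1.33 ± 0.34). In contrast, Myod1 was higher in all 4 KO libraries (0.88 ± 0.16, adjusted p = 0.0037), at 234 CPM ± 39.9 against 127 ± 14.9.

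Of 13780 genes, 1116 were higher and 1368 lower at day 1. The cell adhesion gene Sdk2 had 0 counts in all WT libraries and 18.5 CPM ± 14.6 in the KO, at least 516-fold higher against a floor of 3 counts over the group. If mates of read pairs were counted separately, this bound and all those below are 0.5 times as large. Gap43 had 46.3 CPM ± 22.9 in WT and 0 counts in the KO, at least 1132-fold lower. Chil5 and Clca3b also had 0 counts in the KO, at least 405-fold and 305-fold lower. Rhox5 (9.52), Rspo2 (8.29), Cntn3 (7.73), Meox2 (7.12), the G-protein regulator Rgs4 (7.06 ± 0.73), the potassium channel Kcnj15 (6.88 ± 0.61) and Chmp4c (-8.70) were again or newly among the largest. Magea6 was at 0.0297 CPM in WT and 19.5 in KO. Cdh11, Myo18b, Gzme and Rftn1 were at 31.4, 17.4, 17.0 and 13.8 CPM in WT and at 0.0321, 0.0214, 0.0214 and 0.0214 in KO, where 2 or 3 counts were left. The sarcomere list had 18 of 35 members lower and 0 higher (21 and 0 adjusted over the list alone; median -1.98), with Actc1 at -5.85 ± 0.85 and Tnni1 at -3.56 ± 0.88. For the sarcomere list, camera gave adjusted p = 1.04e-05, and adjusted p = 0.764 with an estimated correlation. Of the Z-disc list 11 were lower and 1 higher (11 and 1 adjusted over the list alone), with Xirp2 (-7.59 ± 0.63) and Ankrd2 (-6.24 ± 1.015). For the Z-disc list, camera gave adjusted p = 0.00115, and adjusted p = 0.763 with an estimated correlation. Fusion genes fell in 7 of 18 cases with 0 higher (8 and 0 adjusted over the list alone), with Itga7 (-1.57 ± 0.35) and Tspan33 (-4.29 ± 0.49), which lies within 1 Mb of Flnc. For the fusion list, camera gave adjusted p = 0.0181, and adjusted p = 0.707 with an estimated correlation. Muscle energy metabolism had 8 of 19 lower and 0 higher (8 and 0 adjusted over the list alone). The mitochondrial coactivator Ppargc1a had 8.54 CPM in WT and 0 counts in the KO, at least 209-fold lower. The glycogen-branching enzyme Gbe1 was at -1.75 ± 0.31. For the energy list, camera gave adjusted p = 0.00928, and adjusted p = 0.707 with an estimated correlation. The hypoxia and glycolysis list had 10 of 25 lower and 0 higher (10 and 0 adjusted over the list alone), with Pfkp (-1.82 ± 0.18), Slc16a3 (-5.40 ± 0.41), Aldoc (-3.91 ± 0.84) and the carbonic anhydrase Car9 (-5.54 ± 1.04). For the hypoxia list, camera gave adjusted p = 8.34e-06, and adjusted p = 0.707 with an estimated correlation. The TGF-beta response list had 8 of 21 higher and 2 lower (8 and 2 adjusted over the list alone). The inhibitors of basic helix-loop-helix factors Id3 (3.43 ± 0.54; 33.8 CPM ± 14.5 in WT, 365 ± 212 in KO) and Id2 (1.20 ± 0.31) and the inhibitory Smad6 (2.26 ± 0.65) were higher, and Ltbp2 was lower (-2.69 ± 0.51). For the TGF-beta list, camera gave adjusted p = 0.0173, and adjusted p = 0.707 with an estimated correlation.

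At day 1 the number of lower sarcomere genes went from 18 to 11, with 2 higher, and that of lower fusion genes from 7 to 4 without WT day 1 replicate 5. The 1 higher Z-disc gene was not called without WT replicate 4 or KO replicate 3 or 5. The list calls were lost for fusion without KO day 1 replicate 3 (adjusted p = 0.181), for muscle energy metabolism without KO replicate 4 (0.0508) and for the TGF-beta response without WT replicate 5 (0.0623) or KO replicate 1 (0.0751) or 4 (0.0640). Blocking by replicate number within the day raised the genes called from 2484 to 3799.

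At day 2 sarcomere genes were lower with a list median of -2.25, and genes of the extracellular matrix and of protein folding differed as well. Actc1, the cardiac actin used by immature muscle, was at 688 CPM ± 216 in WT and 7.61 ± 2.80 in KO (n = 3; -6.50 ± 0.38) and Mymk at 685 ± 139 and 79.6 ± 54.9 (-3.10 ± 0.58). Myog was at 575 ± 104 and 118 ± 10.1 (-2.29 ± 0.15, adjusted p = 0.00997; -2.26 and 0.0508 without KO day 2 replicate 5). Each of these genes was lower in all 3 KO libraries. The matrix protein periostin, Postn, was higher in the KO by 7.15 ± 0.57 (3.84 CPM ± 2.08 to 548 ± 229), Id3 by 5.04 ± 0.53 (11.1 CPM ± 5.54 to 365 ± 125) and Myod1 by 1.015 ± 0.30 (145 CPM ± 49.4 to 293 ± 39.0). The endoplasmic reticulum chaperone Hspa5 was lower by 2.84 ± 0.95 on the log2 scale, with a wide spread between the WT libraries (3650 CPM ± 5476 in WT, 509 ± 143 in KO).

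Of 13780 genes, 1053 were higher and 1414 lower at day 2. Magea6 and Sdk2 had 0 counts in WT and were at least 556-fold and 503-fold higher. Rhox5 (10.07), Rspo2 (9.02), Kcnj15 (8.17), Cntn3 (7.51) and Meox2 (7.07) followed. The phosphatase gene Ppef1 (24.3 CPM in WT) and the genes Cdh11 (21.8), Gap43 (20.8), Clca3b (17.7), Chil5 (12.1) and Gzme (11.9) had 0 counts in the KO, at least 494-, 442-, 422-, 360-, 247- and 242-fold lower. Xirp2 was at 33.7 CPM in WT and 0.0409 in KO and Chmp4c at 22.9 and 0.0292. The sarcomere list had 21 of 35 members lower and 0 higher (24 and 0 adjusted over the list alone), with Myom2 (-3.33 ± 0.48), Tnnt2 (-3.01 ± 0.22) and Tnni1 (-3.72 ± 0.26). For the sarcomere list, camera gave adjusted p = 1.35e-08, and adjusted p = 0.707 with an estimated correlation. The Z-disc list had 11 of 28 lower and 0 higher (11 and 0 adjusted over the list alone), with Ankrd1 (-2.07 ± 0.21) and Myoz2 (-5.24 ± 0.48). For the Z-disc list, camera gave adjusted p = 8.34e-06, and adjusted p = 0.707 with an estimated correlation. Muscle energy metabolism had 6 of 19 lower and 0 higher (8 and 0 adjusted over the list alone), with the fatty acid carrier Fabp3 at -2.10 ± 0.51. For the energy list, camera gave adjusted p = 9.69e-04, and adjusted p = 0.707 with an estimated correlation. The extracellular matrix list had 15 of 38 higher and 5 lower (19 and 6 adjusted over the list alone). The collagen VI chains Col6a2 (5.00 ± 0.39) and Col6a1 (4.52 ± 0.31) were higher, and the proteoglycan Bgn was lower (-6.66 ± 0.60). For the matrix list, camera gave adjusted p = 0.00115, and adjusted p = 0.770 with an estimated correlation. The TGF-beta response list had 6 of 21 higher and 1 lower (7 and 2 adjusted over the list alone), with Id1 (2.23 ± 0.22) and Id2 (1.89 ± 0.27). For the TGF-beta list, camera gave adjusted p = 0.00295, and adjusted p = 0.707 with an estimated correlation. The unfolded protein response list had 16 of 22 lower and 0 higher (19 and 0 adjusted over the list alone; median -1.70), with Herpud1 at -1.89 ± 0.65. For the unfolded protein list, camera gave adjusted p = 3.54e-05, and adjusted p = 0.763 with an estimated correlation. The hypoxia and glycolysis list had 8 of 25 lower and 0 higher (9 and 0 adjusted over the list alone). For the hypoxia list, camera gave adjusted p = 7.97e-06, and adjusted p = 0.707 with an estimated correlation. The interferon list had 8 of 25 lower and 2 higher (11 and 2 adjusted over the list alone), with the apoptosis factor Xaf1 (-3.18 ± 0.40) lower and the immunoproteasome subunit Psmb8 higher (0.0190 CPM in WT, 1.44 in KO). For the interferon list, camera gave adjusted p = 0.0313, and adjusted p = 0.707 with an estimated correlation (0.0558 with a replicate block). The cell cycle list shifted down by a median of 0.92 on the log2 scale (camera adjusted p = 0.00709, and adjusted p = 0.897 with an estimated correlation). Only E2f1 was lower (-1.23 ± 0.21) and only Mcm4 higher among its 40 genes (1 lower and 0 higher adjusted over the list alone).

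The unfolded protein values at day 2 rested largely on WT day 2 replicate 4, whose list level was 2.699 log2 units above the mean of WT day 0. The other WT day 2 libraries were at 0.459, 0.385 and -0.141. Without replicate 4, 3 in place of 16 genes were called, and without KO day 2 replicate 3 or 5 it was 9 or 10. Without KO day 2 replicate 5 the genes called fell from 2467 to 1508, and without KO replicate 3 or 5 the sarcomere genes from 21 to 12. The list call for the cell cycle was lost without WT replicate 3 (0.102) or 5 (0.0686) or KO replicate 1 (0.0756) or 5 (0.0899), and with fry (0.190). That for interferon was lost without WT replicate 4 (0.101) or 5 (0.0630) or KO replicate 1 (0.0821). Halved counts (0.188), a block within each day (0.141) and leaving out the 2 libraries that stand apart (0.0547) ended the interferon call as well. The 8 lower interferon genes became 5 without WT replicate 3 or 4, 4 without KO replicate 1 and 3 without KO replicate 5. The 2 higher became 1 without WT replicate 3 or 5 or KO replicate 3 or 5, and the 5 lower matrix genes were 3 without KO replicate 5.

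At day 4, when WT cultures had reached high contractile gene expression, KO cells held less RNA of many muscle genes. They held more RNA of collagen VI, of Id genes and of Myod1 than WT cells. Myh3 was at 5329 CPM ± 766 in WT and 819 ± 230 in KO (-2.70 ± 0.24, adjusted p = 0.0152) and Mymk at 1704 ± 416 and 397 ± 107 (-2.10 ± 0.25). Cdkn1a was at 3675 ± 1106 and 1582 ± 548 (-1.22 ± 0.31), and the Z-disc crosslinker alpha-actinin-2, Actn2, at 83.6 ± 10.9 and 1.16 ± 1.60 (-6.08 ± 0.75). All 4 genes were lower in 4 of 4 KO libraries. Col6a2 was at 0.793 CPM ± 0.513 in WT and 321 ± 171 in KO (8.63 ± 0.72). Col6a1 was higher by 7.70 ± 0.79, Id3 by 7.43 ± 0.70 (2.60 CPM ± 1.499 to 444 ± 134) and Myod1 by 1.04 ± 0.18 (adjusted p = 4.13e-04). The sterol reductase gene Dhcr7 fell with 14 further cholesterol genes (-2.50 ± 0.20; 158 CPM ± 32.7 to 27.9 ± 5.25).

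Of 13780 genes, 1830 were higher and 1961 lower at day 4. Rspo2 (29.3 CPM in KO) and the genes Sdk2 (12.8) and Meox2 (10.8) had 0 counts in WT and were at least 643-, 281- and 237-fold higher. Kcnj15 (10.81 ± 0.32; 0.103 CPM to 183) and Rhox5 (9.07) followed, and the glutathione transferase Gsta3 and the methyltransferase Inmt went from 0.0300 CPM each to 13.7 and 12.4. The acyltransferase Mboat2 (14.8 CPM in WT) had 0 counts in the KO, at least 302-fold lower. Fras1 and Colec10 went from 14.6 and 15.1 CPM to 0.0270 and 0.0516, and Rftn1 from 12.9 to 0.0516. Dnase1l3 (-8.46), Reep1 (-7.71), Limch1 (-7.21) and the myokine Il15 (-7.07 ± 0.60) were lower. The sarcomere list had 22 of 35 lower and 0 higher (25 and 0 adjusted over the list alone), with Actc1 (-5.54 ± 0.43) and Myl2 (-3.99 ± 0.93). For the sarcomere list, camera gave adjusted p = 2.84e-07, and adjusted p = 0.707 with an estimated correlation. The Z-disc list had 16 of 28 lower and 1 higher (17 and 1 adjusted over the list alone), with Ankrd1 (-2.33 ± 0.22). For the Z-disc list, camera gave adjusted p = 7.26e-07, and adjusted p = 0.707 with an estimated correlation. Excitation-contraction coupling had 11 of 25 lower and 2 higher (12 and 2 adjusted over the list alone), with Casq2 (-3.76 ± 0.23) and Cacnb1 (-1.60 ± 0.14). For the coupling list, camera gave adjusted p = 0.0121, and adjusted p = 0.783 with an estimated correlation. Muscle energy metabolism had 9 of 19 lower and 0 higher (9 and 0 adjusted over the list alone), with Fabp3 (-2.94 ± 0.14) and phosphofructokinase Pfkm (-1.15 ± 0.21). For the energy list, camera gave adjusted p = 7.97e-04, and adjusted p = 0.707 with an estimated correlation. The hypoxia and glycolysis list had 12 of 25 lower and 0 higher (13 and 0 adjusted over the list alone), with Egln3 (-1.61 ± 0.17). For the hypoxia list, camera gave adjusted p = 1.04e-04, and adjusted p = 0.707 with an estimated correlation. Cholesterol synthesis had 15 of 21 lower and 0 higher (17 and 0 adjusted over the list alone; median -1.33), with Sc5d (-1.15 ± 0.20). For the cholesterol list, camera gave adjusted p = 3.39e-06, and adjusted p = 0.707 with an estimated correlation. The extracellular matrix list had 17 of 38 higher and 6 lower (18 and 8 adjusted over the list alone), with Col6a3 (3.58 ± 0.25) and Thbs2 (2.19 ± 0.13) higher. For the matrix list, camera gave adjusted p = 0.00272, and adjusted p = 0.783 with an estimated correlation. The TGF-beta response list had 8 of 21 higher and 3 lower (8 and 4 adjusted over the list alone), with Id1 (3.11 ± 0.28), Id2 (3.28 ± 0.25) and Smad6 (3.11 ± 0.32). For the TGF-beta list, camera gave adjusted p = 0.0475, and adjusted p = 0.763 with an estimated correlation. This last list call was lost with a replicate block (0.0558) and without WT day 4 replicate 4 (0.0817) or KO day 4 replicate 3 (0.0831) or 4 (0.0529). Myog (-1.53 ± 0.33, adjusted p = 0.0365) kept values of -1.40 and -1.49 without WT replicates 3 and 4 and -1.37 and -1.47 without KO replicates 1 and 4, where the adjusted p was 0.0788, 0.0646, 0.0986 and 0.0877. With no filter it was -1.55 (0.0633). The 2 higher coupling genes became 1 without WT replicate 1 or 4 or KO replicate 1 or 5, and 0 without WT replicate 3 or KO replicate 4. The 6 lower matrix genes were 3 without KO replicate 4.

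At day 6, the last day sampled, many muscle genes were still lower in KO cells, while others passed no threshold. Ckm was at 278 CPM ± 98.9 in WT and 179 ± 93.6 in KO (-0.64 ± 0.55, adjusted p = 0.507), and Acta1 at 6236 ± 1544 and 2607 ± 930 (-1.26 ± 0.33, adjusted p = 0.0863). Acta1 was lower in all 4 KO libraries than in all WT libraries and passed the threshold with DESeq2 (0.0431), in a fit of the day 6 libraries alone (0.00283) and with a replicate block within the day (0.0354). From day 0 to day 6 the KO effect changed by 1.43 ± 1.19 for Ckm and 0.01 ± 0.85 for Acta1, with no call (adjusted p = 0.385 and 1). Also compared were Des, the intermediate filament desmin, the co-chaperone Bag3, a partner of filamin C in tension-induced autophagy, and the proliferation marker Mki67. They differed by -0.31 ± 0.19, 0.21 ± 0.19 and 0.19 ± 1.41 and passed no threshold (adjusted p = 0.523, 0.489 and 0.917). Myh3 (-3.09 ± 0.29, adjusted p = 0.00628; 5420 CPM ± 996 to 638 ± 236), the perinatal myosin Myh8 (-4.38 ± 0.48), Mymk (-2.06 ± 0.24), Xirp1 (-2.63 ± 0.16), Cdkn1a (-1.44 ± 0.13) and Actn2 (-6.86 ± 0.43; 134 CPM ± 26.9 to 1.20 ± 0.545) were lower in all 4 KO libraries, and Myod1 was higher in all 4 (0.98 ± 0.13, adjusted p = 7.85e-04).

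Of 13780 genes, 1997 were higher and 1983 lower at day 6. With 0 counts in WT, Rspo2 (33.1 CPM in KO), Inmt (30.1), the interferon-inducible GTPase Iigp1 (17.8) and Magea6 (16.4) were at least 506-, 459-, 272- and 251-fold higher. Kcnj15 (10.27 ± 0.64), Kcnj16, Col15a1 and Gsta3 went from 0.157, 0.0317, 0.0317 and 0.0393 CPM to 176, 29.8, 21.0 and 18.9. With 0 counts in the KO, Mboat2 (20.4 CPM in WT), Colec10 (18.3), the connexin Gja5 (14.3) and the kinase Tnik (13.5) were at least 278-, 250-, 195- and 183-fold lower. Kcnn3 (-8.60), Atp6v1c2 (-8.53), Xirp2 (-8.38 ± 0.65) and Itm2a (16.3 CPM to 0.0332) followed. The sarcomere list had 20 of 35 lower and 0 higher (27 and 0 adjusted over the list alone; median -1.93), with the slow light chain Myl2 (-5.68 ± 0.71; 176 CPM ± 145 to 3.32 ± 1.61), Actc1 (-5.14 ± 0.43) and Tnnt2 (-2.53 ± 0.35). For the sarcomere list, camera gave adjusted p = 2.70e-07, and adjusted p = 0.707 with an estimated correlation. The Z-disc list had 17 of 28 lower and 1 higher (20 and 1 adjusted over the list alone), with Myoz2 (-5.11 ± 0.43). For the Z-disc list, camera gave adjusted p = 5.75e-07, and adjusted p = 0.707 with an estimated correlation. Excitation-contraction coupling had 11 of 25 lower and 2 higher (12 and 2 adjusted over the list alone), with Chrnb1 (-1.24 ± 0.17). For the coupling list, camera gave adjusted p = 0.0203, and adjusted p = 0.788 with an estimated correlation. Muscle energy metabolism had 11 of 19 lower and 1 higher (11 and 1 adjusted over the list alone), with Pfkm (-1.47 ± 0.23). For the energy list, camera gave adjusted p = 1.64e-04, and adjusted p = 0.707 with an estimated correlation. Hypoxia and glycolysis had 12 of 25 lower and 1 higher (13 and 1 adjusted over the list alone), with Egln3 (-1.93 ± 0.18). For the hypoxia list, camera gave adjusted p = 5.33e-04, and adjusted p = 0.707 with an estimated correlation. The extracellular matrix list had 17 of 38 higher and 8 lower (18 and 8 adjusted over the list alone), with Col6a3 (3.87 ± 0.23; 8.88 CPM ± 2.02 to 131 ± 28.6), Col6a2 (8.51 ± 0.83) and Thbs2 (2.51 ± 0.14) higher. For the matrix list, camera gave adjusted p = 0.00711, and adjusted p = 0.788 with an estimated correlation. Col1a1 was lower in all 4 KO libraries (-2.655 ± 0.26, adjusted p = 0.0215; 2.95 CPM ± 0.266 to 0.426 ± 0.1885), at -2.52 (0.0515) without KO day 6 replicate 3 and -2.63 (0.0543) with halved counts. Targets of SRF and MRTF in the actin cytoskeleton had 9 of 25 higher and 3 lower (11 and 3 adjusted over the list alone), with the myosin light chain Myl9 (3.38 ± 0.45), Actg1 (1.68 ± 0.21) and caldesmon, Cald1 (1.10 ± 0.13), higher. For the SRF and MRTF list, camera gave adjusted p = 0.0284, and adjusted p = 0.865 with an estimated correlation. Cholesterol synthesis had 10 of 21 lower and 0 higher (12 and 0 adjusted over the list alone), with Dhcr7 (-2.47 ± 0.28). For the cholesterol list, camera gave adjusted p = 0.00353, and adjusted p = 0.854 with an estimated correlation. The 10 genes became 3 without WT day 6 replicate 5, 5 without WT replicate 3, 6 without KO replicate 4 and 4 without KO replicate 5. The call for excitation-contraction coupling was lost without KO day 6 replicate 4 (0.0503), and that for the SRF and MRTF targets without WT day 6 replicate 1 (0.0540). The 8 lower matrix genes became 4 without KO replicate 3, 4 or 5 and 5 without WT replicate 3. The 1 higher hypoxia gene was lost without each day 6 library except WT replicate 4, and the 1 higher energy gene without each except WT replicate 4 and KO replicate 3.

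**Figure D3:**
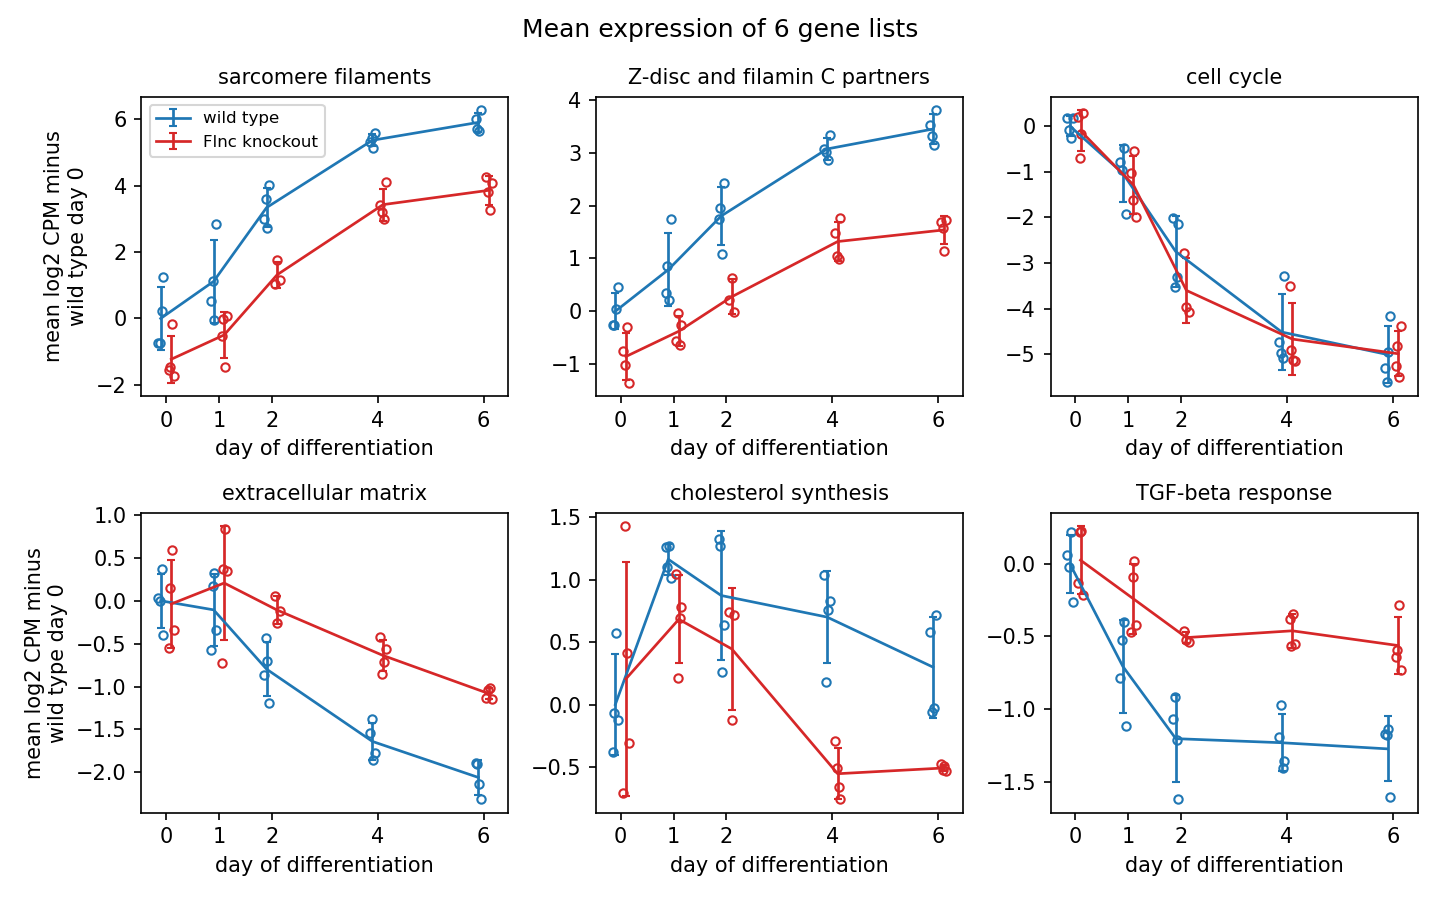
Mean log2 CPM of 6 gene lists by day, as the difference from the mean of WT day 0; points are libraries and lines join group means of WT and KO. In the sarcomere panel the KO line runs below the WT line at each day, with medians of gene differences from -1.45 at day 0 to -1.93 at day 6.

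A set of genes differed in the same direction on every day. All 5 comparisons, which share no library, called 321 genes higher and 504 lower in the KO, where independent lists of these sizes would share 0.106 and 0.261. In total 6036 genes were called on at least 1 day and 108 in both directions on different days. Rhox5, Rspo2, Cntn3 and Kcnj15 were among those higher and Flnc, Xirp1, Xirp2, Mymk, Ankrd1 and Slc16a3 among those lower. Across genes, which are not independent replicates, the KO effects at days 0 and 1 correlated with r = 0.852 (rho 0.793), those at days 4 and 6 with r = 0.881 (rho 0.872) and those at days 0 and 6 with r = 0.560 (rho 0.372).

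Genes of whole chromosomes were shifted together on all 5 days, on 4 of them with a median beyond 0.2 on each day. The median KO minus WT log2 difference was 0.451 to 0.523 on chromosome 16, 0.297 to 0.349 on chromosome 4, -0.403 to -0.323 on chromosome 3 and -0.415 to -0.306 on chromosome 13. In comparison, 1000 random gene sets reached at most 0.0680. Another 5 chromosomes had smaller medians beyond that value on all 5 days: chromosome 2 (-0.239 to -0.154), 5 (-0.172 to -0.0947), 10 (0.1 to 0.212), 11 (0.139 to 0.197) and 15 (0.0738 to 0.142). Of the 825 genes changed the same way on all days, 202 lie on the first 4 chromosomes and 623 off them. Of the genes called, 1586, 1874, 1878, 2995 and 3145 at days 0, 1, 2, 4 and 6 lie elsewhere. Of the genes named here, Sfrp2, Chmp4c, Chil5, Clca3b, Postn, Gja5, Tnik, Kcnn3, Myoz2, Casq2 and Iqgap3 lie on chromosome 3 and Kank4os, Col15a1, Id3, Car9, Fabp3 and Abca1 on chromosome 4. Pfkp, Actn2, Rbm24 and Depdc1b lie on chromosome 13, and Gap43, Kcnj15, Jam2, Gbe1, Mcm4 and Tekt5 on chromosome 16. Xirp2 lies in a stretch of chromosome 2 (59899363 to 70825728) and Actc1 in another (110655201 to 118127133) where windows of 25 neighboring genes had a lower median in the KO on all 5 days. E2f1, Fras1 and Cdc25c lie in further such stretches of chromosomes 2, 5 and 18.

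**Figure D4:**
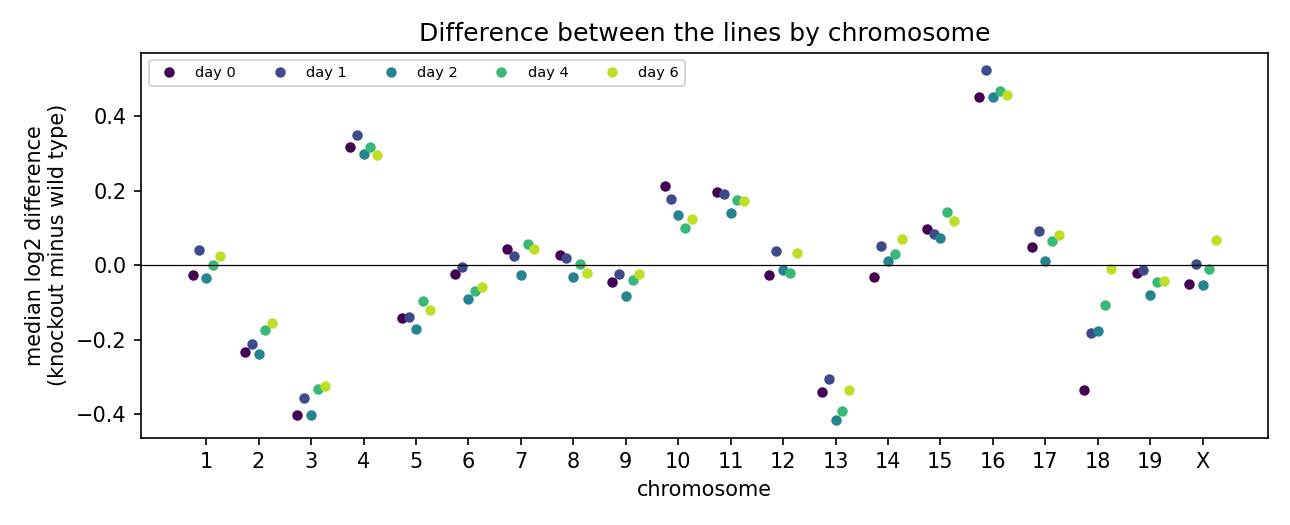
Median KO minus WT log2 difference of the tested genes on each chromosome, with 1 point per day. The medians of chromosomes 16 and 4 lie at 0.451 to 0.523 and 0.297 to 0.349 and those of chromosomes 3 and 13 between -0.415 and -0.306 on all 5 days.

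Differentiation of WT cells was compared with day 0 to follow the normal course. By day 6 the cell cycle genes had gone down and the contractile genes up. All 40 cell cycle genes fell (median -5.57), with Mki67 at -7.04 ± 0.71. Of the list of contractile genes 33 of 35 rose with 0 lower (median 6.14), with Myh3 at 6.40 ± 0.93 and Acta1 at 5.46 ± 0.73. Myog rose by 5.51 ± 0.52 (26.3 CPM ± 19.4 to 1196 ± 328), Mymk by 5.57 ± 0.54 and Cdkn1a by 4.00 ± 0.20, and Flnc by 1.29 ± 0.27. The largest increases were in Chil1, Mybpc2, Isx and Ptgds, which had 2 or 3 counts at day 0, and in the ion transport regulator Fxyd6 (9.83 ± 0.47), Limch1 (9.29), Myl2 (8.89 ± 0.88) and Tceal7 (8.22). The largest decreases were in Ngfr, with 14.0 CPM at day 0 and 0 counts at day 6, Nefl (-9.47 ± 0.58; 389 CPM ± 292 to 0.551 ± 0.116), Cenpm, Smoc2, Selp (-8.22), Mybl2 (-7.73), Cdc25c (-7.70) and Espl1 (-7.61). The number of genes called against day 0 was 577 at day 1 (320 higher, 257 lower), 3521 at day 2 (1645 and 1876), 6028 at day 4 (2681 and 3347) and 6813 at day 6 (2988 and 3825). With camera, cell cycle (adjusted p = 2.13e-23) and sarcomere (1.34e-25) lists were called, and adjusted p = 0.0994 and 0.0715 with an estimated correlation; 40 and 33 genes were called adjusted over the list alone. The extracellular matrix list fell in 29 of 38 genes with 2 higher (29 and 2 adjusted over the list alone). For the matrix list, camera gave adjusted p = 1.41e-07, and adjusted p = 0.1998 with an estimated correlation. The count of 577 at day 1 became 1070 with replicate number as a block, 203 and 337 without WT day 0 replicates 3 and 5, and 289 and 115 without WT day 1 replicates 1 and 5.

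In KO cells, too, cell cycle genes fell and contractile genes rose. All 40 cell cycle genes fell by day 6 (median -5.19; 40 adjusted over the list alone). For the cell cycle list, camera gave adjusted p = 5.76e-29, and adjusted p = 0.0715 with an estimated correlation. Of the sarcomere genes 33 of 35 rose with 0 lower (median 5.83; 33 and 0 adjusted over the list alone). For the sarcomere list, camera gave adjusted p = 5.16e-26, and adjusted p = 0.0715 with an estimated correlation. Myog rose by 6.28 ± 0.97, Mymk by 5.59 ± 0.47, Myh3 by 5.85 ± 0.98, Acta1 by 5.47 ± 0.44, Ckm by 7.03 ± 0.69 and the residual Flnc RNA by 2.01 ± 0.40. The largest increases were in Inmt (0 counts at day 0, 30.1 CPM at day 6), Cox8b and Tekt5, which had 2 or 3 counts at day 0, the muscle caveolin Cav3 (7.95 ± 0.71), the fast myosin Myh1 (7.67 ± 0.80), Sbk2 (7.52), the splicing regulator Rbm24 (7.28 ± 0.79) and Abca1 (7.25). The largest decreases were in Fmod (-8.26), the mitotic kinase Plk1 (-7.95 ± 0.28), Pclaf (-7.90), Pbk (-7.83), Iqgap3 (-7.53) and in Kif14, Sapcd2 and Depdc1b, which kept 2 counts at day 6. Genes called against day 0 were 1101 at day 1 (576 higher, 525 lower), 3665 at day 2 (1750 and 1915), 5174 at day 4 (2468 and 2706) and 6012 at day 6 (2827 and 3185). The count at day 1 was 17 in a fit of the KO day 0 and day 1 libraries alone, 1864 with replicate number as a block, 326, 1671 and 497 without KO day 0 replicates 3, 1 and 5, and 2985, 511 and 372 without KO day 1 replicates 3, 1 and 5. At day 2 it was 2123 without KO day 2 replicate 5.

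The programs of the 2 lines overlapped. At day 6, 1659 genes were higher than at day 0 in both (613 expected by chance) and 2230 lower in both (884 expected). Another 44 rose in WT and fell in KO and 109 did the reverse. Across genes the changes correlated with r = 0.676 (rho 0.654), and the slope of KO on WT changes among genes called in WT was 0.608. This slope was fitted through the origin to genes picked by their WT change. Such picking lowers a slope by itself, so the value does not give the extent of the KO program.

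The comparison of genotype by day asks which differences between the lines grew or shrank from day 0. The KO minus WT difference rose from day 0 for Col6a3, Id2, Id3, the cytoplasmic actin genes Actb and Actg1 and the adhesion molecule Vcam1. It fell for cholesterol and some Z-disc genes. At day 6 the KO effect had risen by 5.44 ± 0.74 for Id3, 3.73 ± 0.38 for Id2, 4.84 ± 0.47 for Vcam1 (WT 115 CPM ± 36.1 at day 0 and 14.0 ± 1.75 at day 6; KO 39.6 ± 24.1 and 139 ± 23.0), 3.41 ± 0.36 for Col6a3, 2.01 ± 0.38 for Actg1 and 1.38 ± 0.20 for Actb. It had fallen by 2.90 ± 0.66 for Dhcr7, 4.39 ± 1.03 for the small heat shock protein Hspb7 and 2.18 ± 0.33 for Pfkm. Cholesterol synthesis genes showed the largest list shift, with 13 of 21 lower and 0 higher at day 4 (18 and 0 adjusted over the list alone; median -1.99). For the cholesterol list, camera gave adjusted p = 2.64e-09, and adjusted p = 0.618 with an estimated correlation. With fry this list was not called (adjusted p = 0.0581). Its mean level relative to WT day 0 varied widely between the KO day 0 libraries, at 0.206 ± 0.937 (SD), against -0.554 ± 0.202 at KO day 4. At day 6, extracellular matrix genes had 12 of 38 higher and 1 lower (15 and 5 adjusted over the list alone). For the matrix list, camera gave adjusted p = 0.00153, and adjusted p = 0.618 with an estimated correlation. SRF and MRTF targets had 9 of 25 higher and 1 lower (12 and 2 adjusted over the list alone). For the SRF and MRTF list, camera gave adjusted p = 7.39e-04, and adjusted p = 0.618 with an estimated correlation. Over all days together 1066 genes were called. Against day 0, edgeR called 75 at day 2 (45 higher, 30 lower), 1056 at day 4 (625 and 431) and 1371 at day 6 (814 and 557). At day 1 edgeR called 0 genes, with 341 at an unadjusted p under 0.05, and DESeq2 called 2. Vcam1 lies on chromosome 3 and Hspb7 on chromosome 4. The count at day 2 was 21 without KO day 2 replicate 5. It was 31 to 49 without each of 8 other libraries, namely WT day 0 replicates 1 and 3, WT day 2 replicate 5, KO day 0 replicates 3, 4 and 5 and KO day 2 replicates 1 and 3.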

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

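The test of the share of myotubes, those of transcript length and depth in KO day 1 replicate 3, and that of copy number on chromosomes 3, 4, 13 and 16 were chosen after the results they address had been seen.

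A test of the difference between days flagged changes of the KO effect. Over all days together 1066 genes were called by this test; against day 0 it was 75 at day 2, 1056 at day 4 and 1371 at day 6, and 0 at day 1, with 341 at an unadjusted p under 0.05 and 2 called by DESeq2. Among the genes with the largest rises of the KO effect at day 6, fitted log2 values were 17.67 for Inmt, 8.839 for Cxcl5, 7.097 for Col15a1, 6.354 for Csf2rb, 5.652 for Hhip, 5.631 for Enpp2 and 5.444 for Id3. Of these Col15a1 and Id3 lie on chromosome 4 and Csf2rb in a stretch of chromosome 15 shifted upward on all 5 days. Fitted values of genes at or near 0 are no bounds, so the levels matter: Inmt had 0.305 CPM in WT day 0, 0 in WT day 6, 0 in KO day 0 and 30.1 in KO day 6. In the same order, Cxcl5 was at 12.9, 0.0945, 2.01 and 7.00 CPM, Csf2rb at 44.8, 1.16, 11.7 and 25.8, Hhip at 55.01, 0.676, 0.140 and 0.0664 and Enpp2 at 2.96, 1.12, 2.57 and 54.2, so the value of Hhip came from its fall in WT alone.

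The largest falls of the KO effect were -9.48 for Mboat2 (1.301 CPM in WT day 0, 20.4 in WT day 6, 0.315 in KO day 0 and 0 in KO day 6), -7.012 for Adamtsl2, -6.898 for Slc26a7, -5.906 for Arhgef6, -5.297 for N4bp3, -5.241 for Aldh1a3, -4.587 for Adamtsl1 and -4.562 for Prrt4, which lies within 1 Mb of Flnc. Slc26a7 and Adamtsl1 lie on chromosome 4. Arhgef6 rose in WT from 0.684 to 86.6 CPM and in KO from 2.96 to 6.07, and N4bp3 from 6.07 to 58.2 in WT while it fell from 5.40 to 1.28 in KO. Of the genes named in advance, Flna (2.177) and Myod1 (0.9983) were flagged in the same way; at 0.7316 to 0.982, Myod1 was not called without WT day 0 replicate 4 (adjusted p = 0.0928), WT day 6 replicate 1 (0.0674) or 4 (0.0622), KO day 0 replicate 3 (0.0669) or 5 (0.0747), or KO day 6 replicate 1 (0.0560), 4 (0.0606) or 5 (0.0545).

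Of the gene lists, those where camera called a changed KO effect are given at the day of their smallest p. At day 4 this was cholesterol synthesis (median -1.989), with 0 genes higher and 13 lower (0 and 18 adjusted over the list alone; adjusted p = 2.64e-09, and adjusted p = 0.618 with an estimated correlation). At day 1 they were the TGF-beta response (0.3306; adjusted p = 1.93e-05, and adjusted p = 0.287 with an estimated correlation), hypoxia and glycolysis (-0.3116), YAP-TEAD targets (0.2981) and neural markers (-0.5969), with 0 genes called in each by edgeR or DESeq2 over all genes or over the list alone, and 3, 2, 2 and 1 at an unadjusted p under 0.05. At day 2 they were the extracellular matrix (0.6499), the unfolded protein response (-1.358), interferon (-0.7037), oxidative phosphorylation (-0.5035), sarcomere filaments (-0.6261) and the cell cycle (-0.8517), with 0, 1, 1, 0, 1 and 0 genes called and 0, 12, 1, 0, 2 and 0 adjusted over the list alone. Of those with 0 called, the matrix list had 9 genes at an unadjusted p under 0.05 and 1 called by DESeq2, and the oxidative phosphorylation and cell cycle lists had 0 and 0. At day 6 they were SRF and MRTF targets (0.7968), the Z-disc (-0.4887), muscle energy metabolism (-0.9336) and the Notch pathway (1.004). Their higher and lower genes were 9 and 1, 1 and 5, 0 and 3, and 5 and 1, and 12 and 2, 1 and 5, 0 and 3, and 6 and 1 adjusted over the list alone. With an estimated correlation none of these was called, with adjusted p from 0.287 to 0.819. Single libraries ended the calls of the unfolded protein response (0.0795 without WT day 2 replicate 4), the cell cycle (0.0511 without WT day 2 replicate 3), sarcomere filaments (0.0687 without KO day 0 replicate 4) and the Notch pathway (0.0598 without KO day 0 replicate 1). The call for YAP-TEAD targets ended without WT replicate 3 of day 0 (0.0563) or day 1 (0.0524), KO day 0 replicate 3 (0.0692) or 5 (0.0747), or KO day 1 replicate 1 (0.111) or 4 (0.1098). That for neural markers ended without WT day 0 replicate 4 (0.0705), KO day 0 replicate 5 (0.0608) or KO day 1 replicate 3 (0.114) or 1 (0.109), with halved counts (0.0846) and with a block within each day (0.0525).

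A library far from the others of its group was flagged 7 times in 153 groups, where chance flags about 1 in 20 groups (7.65). List levels relative to WT day 0 were -0.1803 for sarcomere filaments in KO day 0 replicate 4 (others -1.72 to -1.46), -3.496 for the cell cycle in KO day 4 replicate 3 (others -5.13 to -4.90) and -1.608 for the TGF-beta response in WT day 6 replicate 5 (others -1.18 to -1.14). Oxidative phosphorylation was at 0.7394 in KO day 0 replicate 3 (others 0.230 to 0.260) and 1.083 in KO day 1 replicate 3 (others -0.259 to -0.205). Hypoxia and glycolysis was at -0.7072 in KO day 4 replicate 3 (others -1.03 to -0.999) and -0.8496 in KO day 6 replicate 1 (others -1.23 to -1.17).

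The first pattern weighed is the 825 genes that differed the same way on all 5 days. A delay or advance of differentiation as the whole cause is excluded, since 54.06% of them (446; 95% interval 50.6 to 57.5) had every KO mean outside the range of the 20 WT libraries, against 4.63% of all tested genes. Regional change was weighed by windows of 25 neighboring genes shifted by more than 0.4 on all 5 days. Of the 825 genes, 17.7% (146, 95% interval 15.2 to 20.5) lay in such windows. Over 50% had been set beforehand for that cause and under 10% against it, and the share met neither, so the test is undecided. Most of the genes lay outside such windows, so shifts of that size and width do not account for them. For the 146 genes inside, regional change stays open, and smaller or narrower shifts were not covered. A copy number difference of chromosomes 3, 4, 13 and 16 also stays open: 75.18% of their genes had the sign of the chromosome, against 57.65% on the others, but these chromosomes were picked by that median, so the share decides nothing. Loss of Flnc and other differences between the lines cannot be told apart, since all KO libraries carry the same cell name; whether these cells are a clone or a pool is not given in the sources used here.

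The second pattern is the muscle genes at day 6. Those weighed are the members of the sarcomere, Z-disc and coupling lists that rose strongly in WT by day 4. This leaves out the Z-disc and coupling members called higher at day 6. Of these 65 genes, with a median of -1.656, 39 were called lower and 0 higher. A single common factor for all of them is excluded: their differences, from -6.857 to 1.323, had an SD 3.853 times (95% interval 3.00 to 4.67) their root mean square SE. A smaller share of myotubes would lower them by 1 factor only if the other cells held none of their RNA. Genes with RNA in the other cells would fall less, as Actn3 and Tpm2 (log2 CPM 7.554 and 9.05 at WT day 1) might. The spread therefore cannot decide on a smaller share of myotubes. A delay by a fixed number of days stays undecided. KO day 6 levels lay between the WT day 1 and day 4 means for 87.69% of these genes (57; 77.2 to 94.5), below for 2 and above for 6. The interval includes the 80% set beforehand. The range is also wide for genes picked by their rise in WT, so the share cannot show 1 common delay. Within it, KO Actn2 (log2 CPM 0.238) lay near its WT day 1 mean (0.147) and KO Tcap (4.054) near its WT day 4 mean (4.061). Whether loss of filamin C acts on the muscle genes directly was not tested.

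The third pattern is KO day 1 replicate 3, whose mean correlation with its group was 0.898. Loss of long transcripts in that library may explain it: its deviation correlated with transcript length at -0.6491, outside the range of the other 38 libraries (-0.490 to 0.468). Replicate 3 of WT days 0 and 6 was at 0.220 and 0.365. Other replicate 3 libraries were negative too, such as WT day 1 (-0.490), WT day 2 (-0.469) and KO day 0 (-0.449), so the direction was not particular to this library. Low depth as the whole cause is excluded: the median deviation of the shortest 25% of transcripts lay 1.993 log2 units above that of the longest 25%, against -0.645 to 0.726 in the 8 libraries with fewer counts. No biological explanation was tested.

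Chance was tested with other splits of the same libraries, in fits of the groups of the contrast. The real split was the only 1 of 35 with as many calls for KO against WT on each day, with 1421, 1372, 1941, 3014 and 4562 calls at days 0, 1, 2, 4 and 6 against at most 0, 0, 77, 0 and 0 in other splits. It was also the only 1 for WT days 1, 2, 4 and 6 (314, 2402, 4988 and 6151 against 0) and for KO days 2, 4 and 6 (3644, 4193 and 5956 against 1551, 0 and 0). If the libraries are taken as unpaired, chance is excluded for KO against WT at day 6, WT days 2, 4 and 6 and KO days 4 and 6. In these contrasts not every same-numbered pair passed r = 0.1, which does not show that the libraries are unpaired. Of all same-numbered pairs, 18 of 19 within a day and 57 of 76 within a line passed it. If they are paired, only 8 splits part every pair there too, and chance stays open. For KO against WT at days 0, 1, 2 and 4, WT day 1 and KO day 2 the replicate numbers pair the libraries. There only 8 splits part every pair, too few for a share under 0.05, and the highest of the other 7 gave 0, 0, 77, 0, 0 and 5 calls. The remaining splits keep some libraries of the same number together. For KO day 1 against day 0 chance is not excluded: 2 of 35 splits gave as many as the real 17 calls, and the other, which set KO day 0 replicates 3, 4 and 5 with KO day 1 replicate 3 against the rest, gave 1692. That split keeps some same-numbered libraries together, and of the other 7 splits that part every pair the highest gave 0. For genotype by day over 100 draws, the real grouping included, 1 draw gave as many calls over all days (1066 against 1), at day 2 (75 against 1) and at day 6 (1371 against 256), 3 did at day 4 (1056 against 2149), and 100 did at day 1 (0 against 773). These draws mixed the genotypes within each day, so they also removed the constant difference between the lines. Their counts therefore do not test a change of the KO effect with day by itself.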

How the results depend on the processing

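The following alternatives were chosen after seeing the data: the block within each day, leaving out the 2 libraries that stand apart, and halved counts. DESeq2 size factors, no filter and halved counts moved no count of genes or lists by more than 1.5 times; among single genes and lists, 6, 33 and 11 fell below the threshold and 1029, 992 and 1011 kept direction and side. A prior count of 0.5 was run for the filamin differences of log2 CPM alone, where the 5 of Flnc and the 10 others kept direction and side.

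With DESeq2 the genes called became 971 for WT day 1, and 2, 187 and 1611 for genotype by day at day 1, at day 2 and over all days; 832 single results were unchanged. Testing against a 1.5-fold change lowered counts by its construction: KO against WT to 944, 1187, 1299, 2018 and 2116, WT days to 77, 1536, 3591 and 4303, KO days to 130, 1512, 2617 and 3266, and genotype by day at days 2, 4 and 6 to 4, 497 and 686. A fit of only the groups of the contrast, with fewer samples, gave 1421 and 1372 for KO against WT at days 0 and 1, 314 for WT day 1, 17 for KO day 1, 40 for genotype by day at day 2 and 443 genes changed the same way on all days.

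A replicate block raised WT day 1 to 1070, KO day 1 to 1864 and genotype by day at day 2 to 175. The block within each day raised KO against WT to 3996 and 3799 at days 0 and 1, genotype by day to 473, 2359 and 2968 at days 2, 4 and 6 and 2238 over all days, and genes changed the same way on all days to 1258; it reversed the uncalled Myod1 at day 0 (0.009586) and Mki67 at day 6 (-0.1272). Without the 2 libraries that stand apart, KO against WT at day 0 was 3657, KO day 1 was 3372, and genotype by day was 1, 176, 1608 and 2368 at days 1, 2, 4 and 6; Myod1 at day 0 reversed to 0.2224. The cause of these changes was not tested.

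With an estimated correlation 0 lists were called in each of the 17 contrasts. With fry the calls of the sarcomere (0.0583), excitation-contraction coupling (0.0703) and oxidative phosphorylation (0.239) lists at day 0 and of the cell cycle list at day 2 (0.190) were lost. With fry 10 lists were called for KO against WT at day 1, and 0, 1, 0 and 2 for genotype by day at days 1, 2, 4 and 6.

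Leaving out each library in turn gave 1393 to 2879 genes for KO against WT at day 0 and 1508 to 2257 at day 2, 115 to 715 for WT day 1, 326 to 2985 for KO day 1, 2123 to 4023 for KO day 2, and 0 to 1 and 21 to 93 for genotype by day at days 1 and 2. Lists called for genotype by day at day 4 were 5 to 10, with 5 without WT day 0 replicate 1 or 3 or KO day 4 replicate 1 or 4. Genotype by day at day 1 was 1 without WT day 0 replicate 4. Flnc at day 2 ranged from -4.022 to -3.649, where the exact test with 6 libraries cannot reach 0.05. Uncalled values ranged from -0.4132 to 0.04907 for Flna at day 2, -0.1428 to 0.2212 for Myod1 at day 0 and -0.4998 to 0.9153 for Mki67 at day 6. Of single results, 8344 were unchanged, 599 weaker, 7 stronger and 8 reversed, and genes changed the same way on all days ranged from 645 to 877. At day 6, group means of 11.5 and 10.2 M counts limit genes at low counts.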

Other observations

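The lists not described for day 6 gave no camera call in KO against WT. With fry, 12 lists were called at day 6, among them 4 of these: the TGF-beta response (6.03e-04), the Notch pathway (0.0156), adipocyte (0.00815) and bone and cartilage markers (0.0397), all upward by the direction that fry gives. The mean level of the bone and cartilage list was not higher in the KO, at -1.276 against -1.205 in WT at day 6, relative to WT day 0. With camera adjusted p, myogenic transcription factors had 4 higher and 3 lower of 15 (0.884), myoblast fusion 3 and 7 of 18 (0.367), the dystrophin and integrin list 2 and 6 of 28 (0.175), autophagy 4 and 6 of 32 (0.561) and the cell cycle 3 and 2 of 40 (0.998). Cell cycle exit had 3 and 5 of 16 (0.561), YAP-TEAD targets 5 and 5 of 22 (0.918), the TGF-beta response 10 and 3 of 21 (0.0876), the Notch pathway 8 and 4 of 20 (0.255) and interferon 5 and 4 of 25 (0.985). The unfolded protein response had 0 and 1 of 22 (0.459), and oxidative phosphorylation 0 and 0 of 32 (0.904), with 1 gene at an unadjusted p under 0.05 and 0 called by DESeq2. Among markers of other tissues, adipocyte genes had 2 and 3 of 6 (0.750), bone and cartilage 4 and 2 of 8 (0.595), smooth muscle 2 and 1 of 9 (0.974), blood and endothelium 2 and 0 of 6 (0.457) and neural genes 3 and 3 of 12 (0.929).

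A regional effect of the edit on the neighbors of Flnc was tested. Of 21 tested genes within 1 Mb of Flnc, 1 was called the same way on all 5 days (4.762%, 95% interval 0.120 to 23.8), against 5.99% of all tested genes, so an effect on most neighbors on all 5 days is excluded. Others were called on some days: Tspan33, Impdh1 and Irf5 on 4, Prrt4 on 3, Smo on 2, and Ahcyl2 and Strip2 on 1.

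Levels of the unfolded protein response list at day 2, relative to WT day 0, were 0.459, 0.385, 2.699 and -0.141 in WT replicates 3, 1, 4 and 5, and -0.343, 0.0792 and -0.340 in KO replicates 3, 1 and 5.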
